A study of Mus musculus with 24 samples.

How the data were processed

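ID8 cells were plated at 150000 per well, grown for 24 h in medium with 4% serum and treated for 3 h, and 100 ng of RNA per sample was labelled for the arrays, per the labels' protocols. The series design text states that replicates were made on separate dates and that technical replicates of a treatment were combined before measurement. Of 24 arrays on 3 slides of 8, the labels mark 2 as excluded from the submitters' final analysis (IFN beta at 10 and at 100 IU/ml, replicate 3). The remaining 22 arrays gave 19 biological samples in 7 groups, with the 2 arrays of each untreated sample averaged.

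The scanner files hold 62976 spots per array, of which 59305 are probe spots. Their processed signal is an intensity that was background-subtracted within the array by Agilent Feature Extraction 11.0.1.1, per the file headers, and it is not normalized between arrays. The deposited table of processed values holds log2 numbers, for which the submitters' processing notes name R 3.6.1 and limma 3.42.0, and the steps are not given in the sources used here. In that table every array had the same lowest (-1.57) and highest value (18.5), and medians lay between 5.52 and 5.54. Each of its columns correlated with log2 of the same array's scanner signal at 0.989 to 0.995, and at 0.998 to 1.00 over an intensity of 200, which gave its scale and probe order. The shared range matches quantile normalization, genes were not centred, and whether a constant was subtracted and how background was treated stays unknown.

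For the results, log2 of the processed signal minus each array's 75th percentile was used, following the usual practice for this scanner. Control spots and spots that the scanner software marked as outliers (79 to 280 per array) were left out, 0 spots were saturated, and spots of a probe were averaged. Genes were named through RefSeq accessions against an annotation of GRCm38.p6, used for names only: 32994 of 56605 probes matched, for 22911 genes, and 23611 probes stayed unnamed, so genes such as Mx1 were not examined. A probe was kept if it was well above background in at least 2 samples of at least 1 group, and the probe with the highest mean stood for its gene. Among the 333 genes called at 1000 IU/ml IFN epsilon, 117 had several probes, and in 114 of these all probes had the same sign, with Dennd5b, Gxylt1 and Nsmaf as exceptions. Helz2 at 100 IU/ml of either interferon and Oas2 at 100 IU/ml IFN beta also had a probe of the other sign, and no comparison examined had called probes in opposite directions. A gene that was well above background on 0 arrays of a group has only a bound there, and where some arrays measured a named gene their number is given. Near-identical partners cannot be told apart with certainty: Trim30a and Trim30d, Trim34a and Trim34b, Phf11c and Phf11d, Ifit3 and Ifit3b, Apol9a and Apol9b, Oas1a and Oas1g, the H2 genes, the Gbp family and Tgtp2. H2-K1 had no value in 1 sample of 1000 IU/ml IFN beta.

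Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 12 residual degrees of freedom) in 1 fit over all 7 groups, without a block, and called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were each treatment against untreated cells, IFN epsilon against IFN beta at each dose, 1000 against 10 IU/ml of each interferon, and the interaction of the latter. Every called gene had all samples of a group beyond all samples of the other, an order that chance gives to 10% of genes with 3 against 3 samples and to 20% with 3 against 2. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation (adjusted over the 18 lists), and with fry, whose p says whether a list's genes move on balance in a direction without comparison to other genes. Members were also counted after adjustment over the list alone. The antiviral score was compared by two-sided exact permutation tests. Tables were read with data.table (1.17.8), array blocks were estimated with statmod 1.5.0, and plots were drawn in Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.

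The 18 lists, the design, the rule for naming genes and most alternatives were fixed before the data were examined. The lists were antiviral effectors, nucleic acid sensing, JAK-STAT and IRF signalling, negative feedback of interferon signalling, MHC class I and MHC class II antigen presentation, interferon-inducible GTPases, chemokines and cytokines, interferon genes, apoptosis and cell death, cell cycle and proliferation, NF-kB targets, immune checkpoint and cell surface ligands, ovarian epithelial and mesenchymal markers, leukocyte markers, endothelial, fibroblast and adipocyte markers, stress and immediate early response, and housekeeping. Genes were named in the text if they were among the 10 largest rises or 5 largest falls of a comparison, the 3 largest changes of a list among called genes, or a panel of 14 (Isg15, Ifit1, Irf7, Usp18, Cxcl10, H2-K1, Tap1, Gbp2, Socs1, Cd274, Tnfsf10, Ifnar1, Ifnar2 and a gene that is not reported here), and could then be followed through the other comparisons. B2m, Ifnb1, Dennd5b, Gxylt1 and Nsmaf, and genes lower only with the replicate block, were chosen after their values were seen.

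Replicate numbers mark separate dates, per the series design text, so they pair the samples. Deviations from the group means correlated at 0.42 on average between samples of the same number (46 of 52 pairs over 0.1) and at -0.20 between 102 pairs of different numbers, and all 19 samples correlated best with a sample of their own number. The fit with the number as a block was therefore an alternative, printed where it changes a comparison's count of genes by over 1.5 times or ends a printed call on a list, and for members of the larger changed lists. Further alternatives were other background corrections and scalings, the submitters' processed values, all 24 arrays, other filters and probe rules, the slide as a block, single arrays in place of averages, only the groups compared, array weights, other moderation and thresholds, and leaving out each sample in turn. Chosen after the data were seen were the fits on dates 1 and 2 only (with and without the block), with unnamed features, and with all 24 arrays and the block. The normexp correction (offset 50) was followed by quantile normalization. It used the median signal, because the files hold no mean signal, and this too was chosen after the files were seen.

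The test was tried on simulated data built from the spread of 14394 genes. For 10 IU/ml IFN epsilon against untreated it called 60.8%, 87.6% and 98.4% of genes changed by log2 1, 2 and 4, and 0.0521% of unchanged genes. For 10 IU/ml IFN beta against untreated, with 2 against 3 samples, these shares were 51.6%, 84.0%, 98.8% and 0.0690%. The simulated values were independent and normal with no differences between dates, unlike the arrays. The shares therefore show that the code recovers set changes and are not the power for the real genes.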

Results

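ID8 is a mouse ovarian cancer line grown from surface epithelial cells, and it was used here to ask how interferon (IFN) epsilon acts on tumour cells directly. IFN epsilon is a type I interferon made by the epithelium of the female reproductive tract, and IFN beta is the type I interferon that many cells release on virus infection. Cells received 10, 100 or 1000 IU/ml of recombinant mouse IFN epsilon or IFN beta for 3 h, or the vehicle alone. RNA was measured on 24 single-colour arrays in 7 groups, with 3 biological replicates made on separate dates and 2 arrays per untreated sample. The submitters' labels mark 2 arrays, those of IFN beta at 10 and 100 IU/ml on the third date, as excluded from the final analysis. These groups therefore had 2 samples here and every other group had 3. Without a block, comparisons with these 2 groups set samples of 3 dates against samples of 2, so differences between dates enter their fold changes.

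The 75th percentile of intensity lay between 643.5 and 1222 across arrays, and it was lower on the third date (742 ± 67, SD of 8 arrays) than on the first (1117 ± 98) and the second (1073 ± 58). Between 47.5% and 57.0% of probes were well above background on an array. The median 95% confidence interval of a log2 fold change reached 0.453 to either side with 3 against 3 samples and 0.507 with 3 against 2. The fit behind it had no block and left differences between dates in its spread, so the number of arrays is not the only limit on precision. Values below are log2 fold changes ± SE unless stated otherwise, with limma's adjusted p. Limma tested 14425 genes in 12 comparisons, and 721 of them would have an unadjusted p under 0.05 by chance in each, more than in most comparisons below. With the replicate number as a block, the genes called at 10, 100 and 1000 IU/ml IFN epsilon went from 29, 152 and 333 to 72, 234 and 1170. Low counts of small p in the fit without a block are therefore no measure of how weak a response was. The counts depended on leaving out the 2 marked arrays: with all 24 arrays limma called 71 genes at 1000 IU/ml IFN epsilon and 0 in each of the other 11 comparisons. Both arrays are IFN beta samples, so they are in neither group when IFN epsilon is compared with untreated cells. There they entered the estimate of the spread that all groups share.

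IFN epsilon raised antiviral genes at its lowest dose. At 10 IU/ml, Usp18, which removes Isg15 from proteins and restrains receptor signalling, rose by 3.51 ± 0.44 (n = 3 against 3, adjusted p = 0.00123). Oas3 and Oas2, which sense viral RNA and switch on its decay, rose by 3.18 ± 0.27 and 3.12 ± 0.36. Trim30a (2.85 ± 0.32), a regulator of inflammatory signalling, and Isg15 (2.61 ± 0.39), a ubiquitin-like modifier, rose as well, with adjusted p of 0.000534 and 0.00714. Irf7, a transcription factor that amplifies interferon output, rose by 2.38 ± 0.35, and Irf9, another factor of this family, by 1.23 ± 0.19. Near-identical partners such as Trim30d and Phf11c may share probe signal with Trim30a and Phf11d, so single members of these pairs are uncertain.

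In total 29 genes rose and 0 fell at 10 IU/ml IFN epsilon, all 29 at least 2-fold, and 152 genes had an unadjusted p under 0.05. A fit to only these groups called 1 gene. With the replicate number as a block the count was 72, which included all 29. Among antiviral effectors 11 of 42 measured members rose, 32 when adjusted over the list alone, with a median of 1.56 (camera adjusted p = 5.27e-05 with an estimated correlation). Interferon-inducible GTPases, which attack vacuoles that hold pathogens, had a median of 1.5, and 2 of 18 rose (10 adjusted over the list alone), led by Igtp (2.57 ± 0.44) and Gbp7 (2.38 ± 0.33). In nucleic acid sensing 3 of 20 rose (7 adjusted over the list alone): Dhx58 (2.39 ± 0.24), Ddx58 (1.68 ± 0.26) and Ifi204 (1.05 ± 0.18), with a list median of 0.58, or 0.36 with dim members at their bound. JAK-STAT and IRF signalling had 3 of 21 higher (4 adjusted over the list alone). With the block 28 antiviral effectors, 7 interferon-inducible GTPases, 6 members of nucleic acid sensing and 1 of MHC class I antigen presentation were higher. For MHC class I antigen presentation the median was 0.33 and the camera adjusted p = 0.0113 with an estimated correlation, but 0.138 with the replicate block, and 0 of 24 members rose in limma (2 adjusted over the list alone). In the fixed panel Ifit1 (3.85 ± 0.78, adjusted p = 0.0834) and Tap1 (1.65 ± 0.37, adjusted p = 0.179) missed the threshold, as did Cxcl10, Gbp2, Cd274, Socs1, H2-K1, Tnfsf10 and both receptor chains.

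At 100 IU/ml, IFN epsilon raised genes of antigen presentation, chemokines and cell death. Ifit3 rose by 6.87 ± 0.91 and Ifit1, which binds foreign RNA, by 6.29 ± 0.78 (n = 3 against 3). Cmpk2, a nucleotide kinase, and Rsad2, which makes a chain-terminating nucleotide, rose by 6.37 ± 0.70 and 5.91 ± 1.22. The chemokine Cxcl10, which draws T cells, rose by 4.43 ± 0.62 (adjusted p = 0.000959). Nlrc5, which drives MHC class I transcription, and Tap1, which carries peptides to it, rose by 3.65 ± 0.50 and 3.40 ± 0.37. Iigp1 was not well above background in untreated cells, so its fold change has only a bound, taken against the higher of its own signal and the lowest detected signal on each untreated array. On that basis Iigp1 was at least 78.8-fold higher, and the death ligand Tnfsf10 (TRAIL) at least 13.6-fold.

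In total 152 genes rose and 0 fell at 100 IU/ml IFN epsilon, 141 at least 2-fold, and 483 genes had an unadjusted p under 0.05. The replicate block gave 234, of which 21 were lower, and kept 150 of the 152. Among antiviral effectors 35 of 42 rose (40 adjusted over the list alone; median 2.81), and among interferon-inducible GTPases 12 of 18 (16 adjusted over the list alone; median 3.63). MHC class I antigen presentation had 8 of 24 members higher (18 adjusted over the list alone; median 1.00), including Psmb9 (2.69 ± 0.38), a subunit of the immunoproteasome. Nucleic acid sensing had 7 of 20 higher (10 adjusted over the list alone), led by Zbp1 (4.44 ± 0.60) and Dhx58 (3.90 ± 0.24), and JAK-STAT and IRF signalling 5 of 21 (5 adjusted over the list alone). Apoptosis and cell death had 3 of 36 higher (6 adjusted over the list alone), among them Pml (1.41 ± 0.21) and Mlkl (1.13 ± 0.24), the latter an executor of necroptosis. Immune checkpoint and cell surface ligands had 2 of 20 higher (4 adjusted over the list alone), Lgals9 (1.40 ± 0.31) and Ly6e (1.13 ± 0.23). Chemokines and cytokines had 3 of 27 higher (3 adjusted over the list alone), and their camera adjusted p = 0.0305 with an estimated correlation became 0.054 with the replicate block. Negative feedback of interferon signalling had 2 of 17 higher (3 adjusted over the list alone), Usp18 (5.18 ± 0.44) and Usp25 (0.89 ± 0.16). That list's mean was 0.43 and its test pointed up while its median was -0.03, and its camera adjusted p = 0.0228 with an estimated correlation became 0.168 with the block. With the block 12 members of MHC class I antigen presentation, 5 of apoptosis and cell death, 3 of immune checkpoint and cell surface ligands and 2 of chemokines and cytokines were higher, and 1 each of MHC class II antigen presentation, cell cycle and proliferation, and endothelial, fibroblast and adipocyte markers.

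At 1000 IU/ml IFN epsilon, Iigp1 was at least 383-fold higher than in untreated cells and Ifit1bl1 at least 286-fold. Tnfsf10 was at least 44.3-fold higher. Cd274, which encodes the checkpoint ligand PD-L1, rose by 5.27 ± 1.17 (n = 3 against 3, adjusted p = 0.0242), and the T cell chemokine Cxcl9 was at least 3.6-fold higher (adjusted p = 0.0449). H2-K1, a classical MHC class I heavy chain, rose by 1.14 ± 0.26, B2m, its light chain and chosen after its values were seen, by 0.84, and Tap1 by 3.95 ± 0.37. The falls were smaller, with Trem1, an activating receptor of myeloid cells, at -1.14 ± 0.19 (adjusted p = 0.00316).

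In total 323 genes rose and 10 fell at 1000 IU/ml IFN epsilon. A change of at least 2-fold was seen in 287 of those that rose and in 1 that fell, and 1138 genes had an unadjusted p under 0.05. Median scaling gave 173 genes in all. With the replicate block 653 genes rose and 517 fell, among them all 333. Besides Trem1, the larger falls were Zc3hav1l (-0.82 ± 0.17), Fam199x (-0.80 ± 0.18), Grasp (-0.78 ± 0.15) and Fzd9 (-0.76 ± 0.19, adjusted p = 0.0492). Fzd9 lost its call under each of the 4 other scalings and Fam199x under 2 of them. Among antiviral effectors 40 of 42 rose (40 adjusted over the list alone; median 3.41), among interferon-inducible GTPases 17 of 18 (17 adjusted over the list alone; median 4.54), and in MHC class I antigen presentation 17 of 24 (20 adjusted over the list alone; median 1.32). Nucleic acid sensing had 11 of 20 higher (14 adjusted over the list alone; median 1.91, or 1.78 with dim members at their bound), including the endosomal RNA receptor Tlr3 (4.59 ± 0.48). JAK-STAT and IRF signalling had 7 of 21 higher (9 adjusted over the list alone), led by Batf2 (5.51 ± 0.72). Untreated cells had Tlr3 well above background on 5 of 6 arrays and Batf2 on 4 of 6.

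Cell death genes at 1000 IU/ml IFN epsilon included Daxx (2.39 ± 0.40), a histone chaperone linked to Fas signalling, and the inflammatory caspases Casp4 (2.03 ± 0.36) and Casp1 (1.62 ± 0.30), within 8 of 36 members higher (9 adjusted over the list alone). In immune checkpoint and cell surface ligands 6 of 20 rose (8 adjusted over the list alone), with Ly6a at 3.92 ± 0.62 and Ly6c1 at 2.77 ± 0.47. In chemokines and cytokines 6 of 27 rose (6 adjusted over the list alone), among them Il18bp (2.69 ± 0.37), which binds and blocks IL-18. Negative feedback had 3 of 17 higher (4 adjusted over the list alone), Usp18 (5.63 ± 0.44), Trafd1 (1.79 ± 0.33) and Usp25 (1.40 ± 0.16), with a mean of 0.60, a median of -0.01 and a camera adjusted p = 0.0575 with an estimated correlation. Socs1, another inhibitor in this pathway, changed by 2.44 ± 0.75 and missed the threshold (adjusted p = 0.186). MHC class II antigen presentation had 2 of 10 higher (3 adjusted over the list alone), the protease Ctss (at least 1.17-fold, well above background on 2 of 3 treated arrays) and the factor Rfx5 (0.99 ± 0.22), with a camera adjusted p = 0.0577 with an estimated correlation. Among NF-kB targets 2 of 25 rose (2 adjusted over the list alone), Nos2 (2.25 ± 0.48) and the adhesion molecule Vcam1 (0.96 ± 0.17). Nos2 and Ly6a were well above background on 4 of 6 untreated arrays. With the block 12 chemokines and cytokines, 5 NF-kB targets and 3 members of MHC class II antigen presentation were higher, and apoptosis and cell death had 13 higher and 3 lower.

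**Figure D1:**
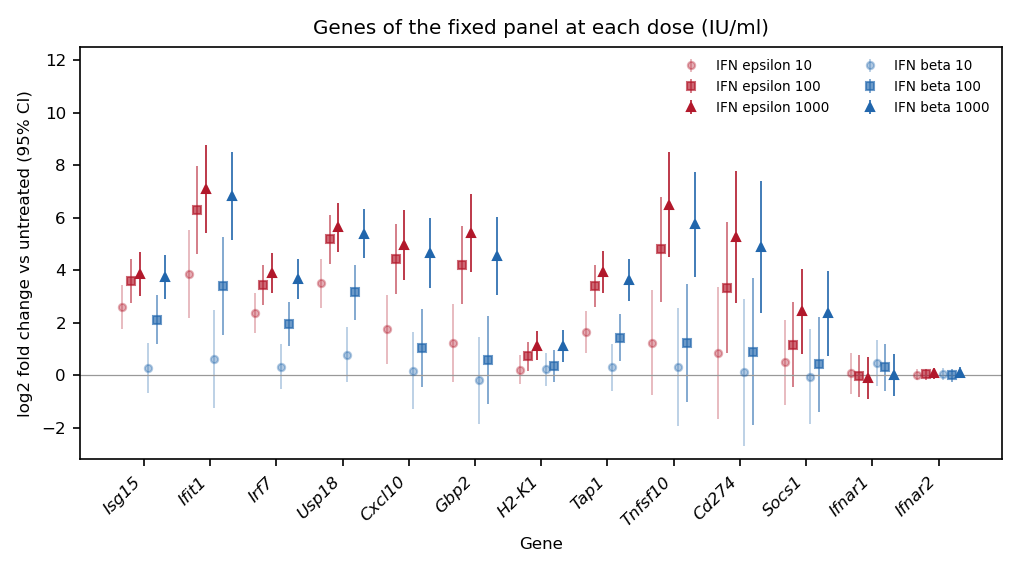
Log2 fold change against untreated cells (vertical axis, with 95% confidence intervals) of 13 genes of the fixed panel at each dose in IU/ml, with IFN epsilon in red and IFN beta in blue. Isg15 stood at 2.61, 3.6 and 3.86 with 10, 100 and 1000 IU/ml IFN epsilon and at 0.28, 2.12 and 3.74 with IFN beta, while both receptor chains stayed near 0.

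IFN beta at 10 IU/ml gave small differences in antiviral genes that passed no test. Usp18 differed by 0.78 ± 0.49, Isg15 by 0.28 ± 0.44 and Irf7 by 0.33 ± 0.40 (n = 2 against 3). Within dates 1 and 2 the differences were 0.93 and 1.27 for Usp18, 0.64 and 0.84 for Isg15 and 0.42 and 0.92 for Irf7. Limma called 0 genes, and 48 genes had an unadjusted p under 0.05. Leaving out an IFN beta sample left a single sample in the group, so no count is given for it here. The antiviral median was 0.38 without the IFN beta sample of the second date and 0.12 without the untreated sample of that date. Antiviral effectors had a median of 0.27 with 0 of 42 members higher (0 adjusted over the list alone). Their camera adjusted p = 2.31e-08 with the preset correlation was 0.775 with an estimated correlation, and MHC class I antigen presentation (median 0.17; 0 of 24 higher, 0 adjusted over the list alone) lost its call at the same value.

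IFN beta at 100 IU/ml raised a core of antiviral genes. Usp18 rose by 3.16 ± 0.49 (n = 2 against 3, adjusted p = 0.0177), Oas2 by 3.05 ± 0.40, Oas3 by 2.63 ± 0.30 and Ifi44, an inhibitor of virus replication, by 2.19 ± 0.30. The RNA sensor Dhx58 rose by 2.01 ± 0.27 (adjusted p = 0.00796). In the panel Ifit1 (3.39 ± 0.87), Isg15 (2.12 ± 0.44) and Irf7 (1.96 ± 0.40) missed the threshold, with adjusted p of 0.567, 0.172 and 0.141. In total 16 genes rose and 0 fell, all 16 at least 2-fold, with 183 genes at an unadjusted p under 0.05. Limma called 0 after median scaling of the arrays and 0 in a fit to only these groups. The block gave 42 genes higher. The count was 10 without the untreated sample of the first date and 7 without that of the second. Leaving out an IFN beta sample left a single sample in the group. The antiviral median was then 1.43 without that of the first date and 1.25 without that of the second.

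Antiviral effectors at 100 IU/ml IFN beta had 7 of 42 members higher (27 adjusted over the list alone) and a median of 1.47, or 1.32 with dim members at their bound (camera adjusted p = 0.00128 with an estimated correlation). JAK-STAT and IRF signalling had 0 of 21 higher (4 adjusted over the list alone) and nucleic acid sensing 1 of 20 (3 adjusted over the list alone). Their camera calls held with an estimated correlation (adjusted p = 0.00492 and 0.00677) and were lost with the block (both 0.0587). Negative feedback, with Usp18 as its 1 higher member of 17 (1 adjusted over the list alone), went from 0.0272 to 0.143 in the same way. For MHC class I antigen presentation (0 of 24; 0 adjusted over the list alone) and interferon-inducible GTPases (0 of 18; 5 adjusted over the list alone) the camera adjusted p = 0.0821 and 0.0681 with an estimated correlation. With the block 17 antiviral effectors, 4 members of nucleic acid sensing, 4 interferon-inducible GTPases and 3 members of JAK-STAT and IRF signalling were higher.

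At 1000 IU/ml IFN beta, Iigp1 was at least 138-fold higher than in untreated cells and Tnfsf10 at least 26.3-fold. Ifit3 rose by 7.30 ± 0.91, Rsad2 by 7.37 ± 1.22, Ifit1 by 6.83 ± 0.78, Usp18 by 5.4 ± 0.44 and Cxcl10 by 4.65 ± 0.62 (n = 3 against 3). Tap1 rose by 3.62 ± 0.37 and the MHC class I regulator Nlrc5 by 4.31 ± 0.50. Cd274 (4.90 ± 1.17, adjusted p = 0.0547) and H2-K1 (1.11 ± 0.29, adjusted p = 0.0982) missed the threshold. Among the falls was the kinase Map3k9 at -0.58 ± 0.13 (adjusted p = 0.0422). Zfp174, a zinc finger protein, was at least 1.28-fold lower (adjusted p = 0.0346), as it was not well above background with 1000 IU/ml IFN beta, and it was on only 3 of 6 untreated arrays.

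In total 228 genes rose and 2 fell at 1000 IU/ml IFN beta, with 207 and 1 of these at least 2-fold, and 788 genes had an unadjusted p under 0.05. Median scaling gave 145 genes and a fit to only these groups 58. The replicate block gave 403 higher and 94 lower. Antiviral effectors had 39 of 42 members higher (40 adjusted over the list alone; median 3.18), interferon-inducible GTPases 16 of 18 (17 adjusted over the list alone; median 4.20) and MHC class I antigen presentation 13 of 24 (19 adjusted over the list alone; median 1.20). Nucleic acid sensing had 9 of 20 higher (12 adjusted over the list alone), JAK-STAT and IRF signalling 6 of 21 (9 adjusted over the list alone) and apoptosis and cell death 5 of 36 (9 adjusted over the list alone). Immune checkpoint and cell surface ligands had 5 of 20 higher (7 adjusted over the list alone), among them Tnfsf4 (2.04 ± 0.47), the ligand of OX40, which was well above background on 1 of 6 untreated and 2 of 3 treated arrays. In chemokines and cytokines 2 of 27 rose (4 adjusted over the list alone), Cxcl10 and Il18bp. Negative feedback had 3 of 17 higher (4 adjusted over the list alone), and its camera adjusted p = 0.00622 with an estimated correlation became 0.0616 with the block. With the block 10 members of apoptosis and cell death were higher, and chemokines and cytokines had 3 higher and 1 lower.

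**Figure D2:**
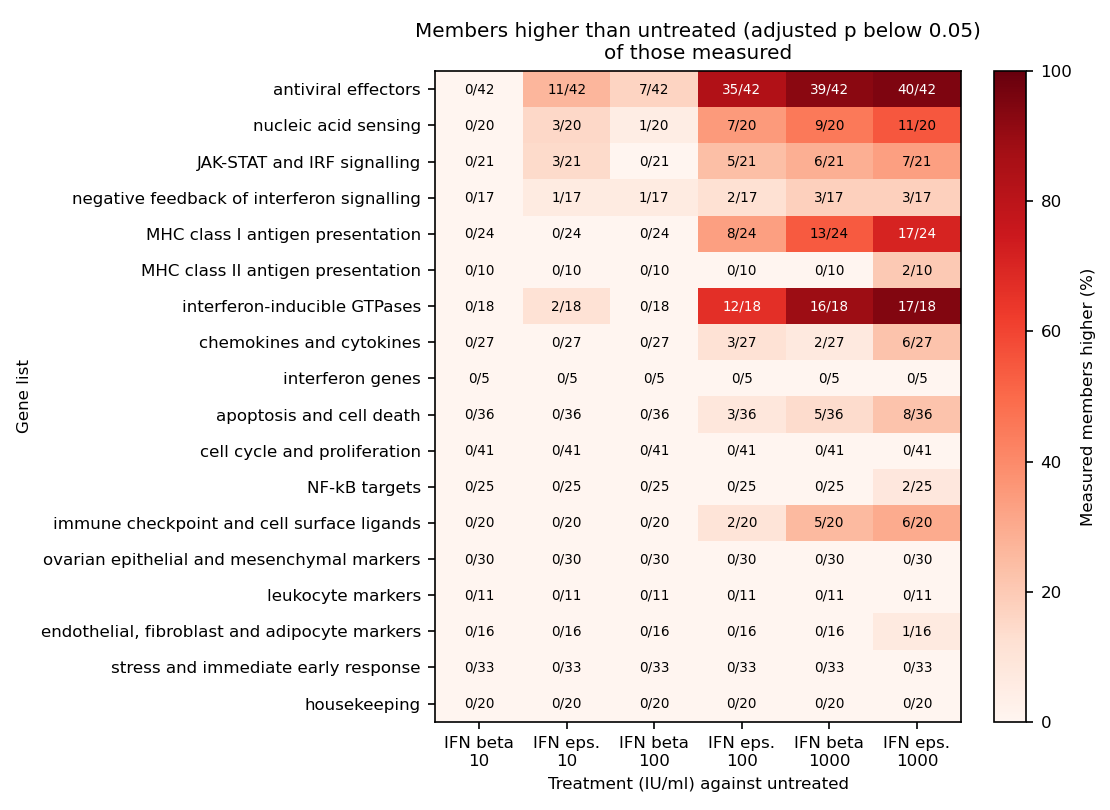
Members of each of the 18 fixed gene lists that were higher than in untreated cells (limma adjusted p below 0.05) as a share of those measured, for each interferon and dose in IU/ml. Antiviral effectors went from 11 of 42 with 10 IU/ml IFN epsilon to 40 of 42 with 1000, and from 0 to 39 with IFN beta.

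The direct comparison at 10 IU/ml asked whether equal doses of the interferons gave equal responses. Trim30a was higher with IFN epsilon than with IFN beta by 2.62 ± 0.35, Oas3 by 2.51 ± 0.30, Gbp7, a guanylate-binding GTPase, by 2.15 ± 0.37, Ifi44 by 2.00 ± 0.30 and Dhx58 by 2.00 ± 0.27 (n = 3 against 2, adjusted p from 0.0118 to 0.044). Usp18 (2.73 ± 0.49, adjusted p = 0.0575) and Isg15 (2.33 ± 0.44, adjusted p = 0.0751) missed the threshold. In total 14 genes were higher with IFN epsilon and 0 with IFN beta, and 137 had an unadjusted p under 0.05. Limma called 0 genes after median scaling of the arrays and 0 in a fit to only these groups. With the replicate block 17 genes were higher with IFN epsilon, among them 10 of the 14, and Gbp7 had an adjusted p of 0.0527. The count was 0 without the IFN epsilon sample of date 2 or date 3. Leaving out an IFN beta sample left a single sample in its group, so no count is given for it here. With each sample left out in turn, the median difference of antiviral effectors ranged from 1.079 to 1.435. Antiviral effectors had 5 of 42 members higher (30 adjusted over the list alone) and a median difference of 1.28 (camera adjusted p = 0.00174 with an estimated correlation). Interferon-inducible GTPases (1 of 18; 8 adjusted over the list alone), nucleic acid sensing (1 of 20; 5 adjusted over the list alone) and JAK-STAT and IRF signalling (1 of 21; 4 adjusted over the list alone) had a camera adjusted p = 0.0285, 0.0151 and 0.0189 with an estimated correlation, and 0.0732, 0.0732 and 0.0658 with the block, where 0, 2 and 1 of their members were higher and 1 member of negative feedback was. MHC class I antigen presentation had 0 of 24 (0 adjusted over the list alone) and an adjusted p = 0.271 with an estimated correlation.

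At 100 IU/ml, 6 of the 13 genes higher with IFN epsilon than with IFN beta were antiviral effectors. Gbp7 differed by 2.74 ± 0.37, Trim30a by 2.65 ± 0.35, Oas3 by 2.33 ± 0.30 and Herc6, which attaches Isg15 to proteins, by 2.15 ± 0.35 (n = 3 against 2, adjusted p from 0.00744 to 0.0285). Iigp1 (6.33 ± 1.15, well above background on 1 of 2 IFN beta arrays), Cxcl10 (3.39 ± 0.69) and Tap1 (1.97 ± 0.42) missed the threshold, with adjusted p of 0.0666, 0.116 and 0.127. In total 13 genes were higher with IFN epsilon and 0 with IFN beta, and 420 had an unadjusted p under 0.05. Limma called 0 after median scaling and 0 in a fit to only these groups, but 35 with the submitters' processed values and 38 after normexp together with quantile normalization. The block gave 53 genes higher with IFN epsilon. Without the IFN epsilon sample of the second date the count was 0, and without that of date 3 it was 8. Leaving out an IFN beta sample left a single sample in its group, so no count is given for it here. With each sample left out in turn, the median difference of antiviral effectors ranged from 1.311 to 1.569. Antiviral effectors had 6 of 42 members higher (32 adjusted over the list alone; median 1.40), interferon-inducible GTPases 1 of 18 (15 adjusted over the list alone; median 2.36), nucleic acid sensing 2 of 20 (7 adjusted over the list alone) and MHC class I antigen presentation 0 of 24 (11 adjusted over the list alone; median 0.65). These 4 lists kept their camera calls with an estimated correlation (largest adjusted p = 0.00777), although with the block MHC class I antigen presentation had 0.0545. With the block 18 antiviral effectors, 8 interferon-inducible GTPases, 6 members of nucleic acid sensing and 1 each of MHC class I antigen presentation and chemokines and cytokines were higher. For JAK-STAT and IRF signalling, chemokines and cytokines, apoptosis and cell death, immune checkpoint and cell surface ligands, and cell cycle and proliferation, the preset calls gave way to adjusted p = 0.109, 0.132, 0.105, 0.0787 and 0.671 with an estimated correlation.

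At 1000 IU/ml no gene passed the direct comparison of the interferons. Ifit1 differed by 0.28 ± 0.78, Isg15 by 0.12 ± 0.39, Cxcl10 by 0.31 ± 0.62 and Cd274 by 0.38 ± 1.17 (n = 3 against 3). Within dates 1, 2 and 3 Iigp1 differed by 3.54, 2.29 and -1.39 and Cd274 by 1.45, 0.58 and -0.91, and 68 of 79 named genes were higher with IFN epsilon on dates 1 and 2 and lower on date 3. Dates 1 and 2 alone gave 14 genes, 11 higher and 3 lower with IFN epsilon, or 57 with the block, 49 higher and 8 lower. Limma called 0 genes (smallest adjusted p = 0.682), and 192 had an unadjusted p under 0.05. The count was 6 without the IFN epsilon sample of the first date, 4 without that of the second and 10, 8 higher and 2 lower with IFN epsilon, without the IFN beta sample of date 3. Antiviral effectors had a median difference of 0.23 and interferon-inducible GTPases of 0.50, and 7 of the 18 lists passed camera with the preset correlation but 0 with an estimated correlation (adjusted p = 0.397 for both lists and for nucleic acid sensing, MHC class I and class II antigen presentation and chemokines, and 0.75 for cell cycle and proliferation). Of the 228 genes higher with IFN beta, 226 were also higher with IFN epsilon, against 5.11 for independent lists, and these were 70.0% of the 323 higher with IFN epsilon. Fold changes of both treatments correlated across genes at 0.892, against a mean of 0.498 in 100 simulations of unchanged groups that shared the untreated samples. Their covariance was 0.251, against 0.0560 in the simulations, a difference of 0.195.

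**Figure D3:**
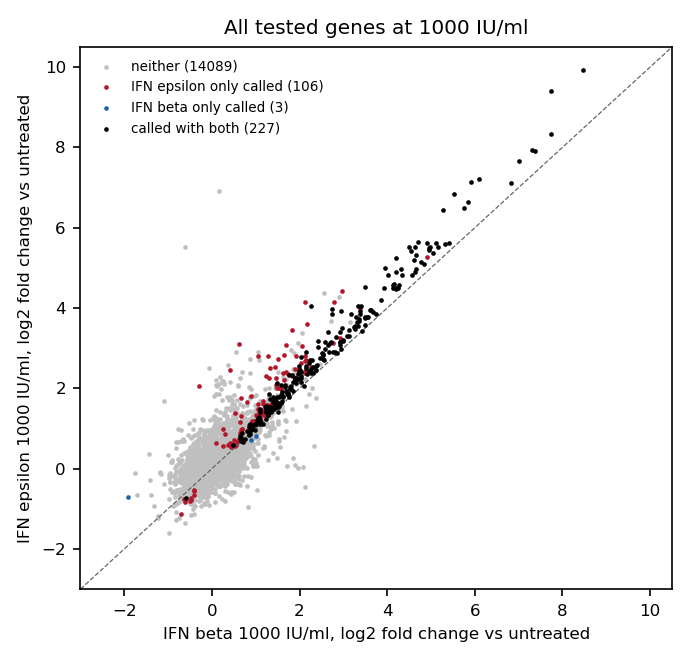
Log2 fold change against untreated cells of all 14425 tested genes at 1000 IU/ml, with IFN beta on the horizontal and IFN epsilon on the vertical axis and the line of equal change dashed. Iigp1, not well above background in untreated cells, lay at 8.46 and 9.94 on these axes and Ifit1 at 6.83 and 7.10.

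Between 10 and 1000 IU/ml IFN epsilon, GTPases, antiviral genes and the death ligand Tnfsf10 were among the genes that rose most. Iigp1 rose by a further 6.89 ± 1.03, Ifit1bl1 by 6.04 ± 1.04, Rsad2 by 5.37 ± 1.22, Tnfsf10 (well above background on 2 of 3 arrays at 10 IU/ml) by 5.25 ± 0.94, Gbp5, a guanylate-binding protein, by 5.16 ± 0.76, Batf2 by 4.11 ± 0.72, Nlrc5 by 3.44 ± 0.50 and Cxcl10 by 3.20 ± 0.62 (n = 3 against 3). Dnmt3a, a DNA methyltransferase, changed by -0.53 ± 0.12 and Trem1 by -1.0 ± 0.19. In total 201 genes rose and 2 fell, 183 of the former at least 2-fold, with 911 at an unadjusted p under 0.05. The block gave 489 higher and 168 lower, and median scaling of the arrays 69 genes in all. Leaving out an IFN epsilon sample at 1000 IU/ml gave 120, 118 or 118 on dates 1, 2 and 3, and leaving out a sample at 10 IU/ml gave 82, 109 or 124. Antiviral effectors had 25 of 42 members higher (40 adjusted over the list alone), interferon-inducible GTPases 14 of 18 (17 adjusted over the list alone) and MHC class I antigen presentation 9 of 24 (19 adjusted over the list alone). The call on MHC class II antigen presentation, with Ctss as its 1 higher member of 10 (3 adjusted over the list alone), had an adjusted p = 0.0935 with an estimated correlation. JAK-STAT and IRF signalling (2 of 21 higher, 7 adjusted over the list alone) and NF-kB targets (1 of 25, 2 adjusted over the list alone) went from a camera adjusted p = 0.0093 and 0.0456 with an estimated correlation to 0.0597 and 0.133 with the block. With the block 40 antiviral effectors, 15 members of MHC class I antigen presentation, 6 of JAK-STAT and IRF signalling and 2 NF-kB targets were higher, and 2 members of MHC class II antigen presentation.

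With IFN beta the step from 10 to 1000 IU/ml raised Ifit3 by 7.19 ± 1.02, Rsad2 by 6.74 ± 1.36, Cmpk2 by 6.25 ± 0.78, Usp18 by 4.62 ± 0.49 and Isg15 by 3.47 ± 0.44 (n = 3 against 2). Iigp1 was at least 143-fold higher and Tnfsf10 at least 27.3-fold. In total 163 genes rose and 0 fell, 158 at least 2-fold, with 682 at an unadjusted p under 0.05. The block gave 231 higher and 22 lower, among them 161 of the 163, median scaling 105 genes and a fit to only these groups 19. Antiviral effectors had 33 of 42 members higher (40 adjusted over the list alone), interferon-inducible GTPases 15 of 18 (17 adjusted over the list alone) and MHC class I antigen presentation 10 of 24 (18 adjusted over the list alone). MHC class II antigen presentation and interferon genes had adjusted p = 0.145 and 0.135 with an estimated correlation. The interaction of interferon and dose asked whether this step differed between the interferons. For it limma called 0 genes, with 131 at an unadjusted p under 0.05, and the count was 2 without the IFN epsilon 1000 IU/ml sample of the second date. Leaving out an IFN beta 10 IU/ml sample left a single sample in that group, so no count is given for it here. Antiviral effectors had a median interaction of -1.13 (0 of 42 members called, 8 lower adjusted over the list alone), toward a smaller step with IFN epsilon. The camera adjusted p = 0.0362 with an estimated correlation became 0.179 with the replicate block, where the median was -0.83. The fry adjusted p was 0.382 without the block. That fit had the third date in the IFN beta 1000 IU/ml group but not in the 10 IU/ml group. Nucleic acid sensing, JAK-STAT and IRF signalling, interferon-inducible GTPases, and cell cycle and proliferation lost their preset interaction calls, at adjusted p = 0.222, 0.0989, 0.34 and 0.809 with an estimated correlation.

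The antiviral score, the mean log2 change of 42 measured antiviral effectors per sample, was 1.72 ± 0.34 (SD, n = 3), 3.14 ± 0.40 and 3.78 ± 0.13 with 10, 100 and 1000 IU/ml IFN epsilon. It was 0.33 ± 0.12 (n = 2), 1.43 ± 0.17 (n = 2) and 3.48 ± 0.66 (n = 3) with IFN beta, and the untreated SD was 0.25. IFN epsilon exceeded IFN beta by 1.40 at 10 IU/ml (95% confidence interval 0.66 to 2.13) and by 1.71 at 100 (0.97 to 2.44), in both dates that held both groups, with differences within dates of 0.95 to 1.54 and 1.36 to 1.82. At 1000 IU/ml the difference was 0.30 (-0.36 to 0.95), higher in 2 of 3 dates and between -0.48 and 0.78 within dates. The two-sided exact permutation p was 0.5 for that difference, 0.2 for 10 IU/ml IFN beta against untreated, and 0.1 for the other 9 comparisons, and 0.1 is the smallest p this design allows (adjusted over 11 comparisons, 0.5, 0.22 and 0.122). Within slides the score differed from untreated arrays by 1.54 and 2.05 with 10 IU/ml IFN epsilon and by 0.09 and 0.68 with 10 IU/ml IFN beta on the same slides.

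**Figure D4:**
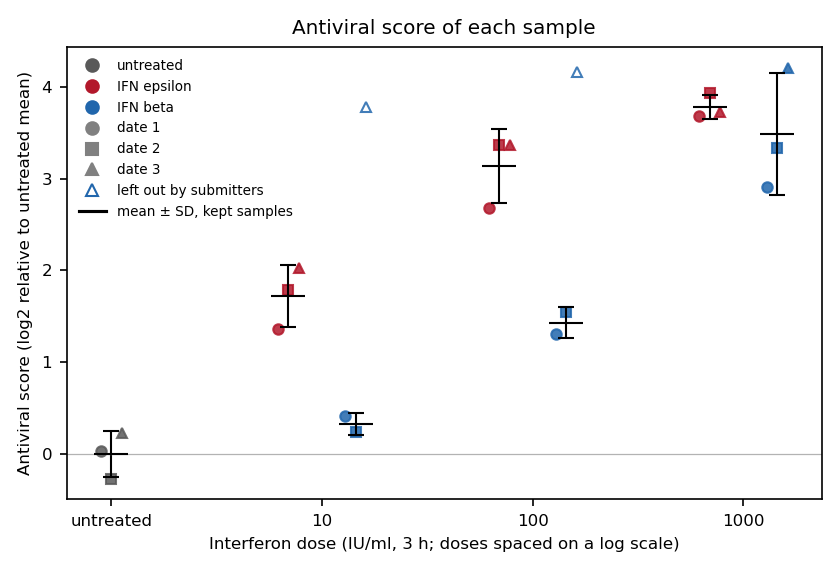
Antiviral score of each sample (log2 relative to the untreated mean) against dose in IU/ml, with symbols for the dates, bars for the mean ± SD of the samples used and open symbols for the 2 arrays left out. IFN epsilon means were 1.72, 3.14 and 3.78 and IFN beta means 0.33, 1.43 and 3.48.

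The receptor genes and most lists outside the interferon response passed no test against untreated cells without the block. Ifnar1 and Ifnar2, the chains of the shared receptor, changed by -0.10 ± 0.37 and 0.09 ± 0.10 at 1000 IU/ml IFN epsilon and by 0.02 ± 0.37 and 0.10 ± 0.10 at 1000 IU/ml IFN beta. At these doses the medians were -0.08 and -0.02 for cell cycle and proliferation, -0.06 and -0.05 for housekeeping, 0.04 and 0.01 for stress and immediate early response, -0.04 and 0.00 for ovarian epithelial and mesenchymal markers, and 0.12 and 0.06 for leukocyte markers, each with 0 members called in limma (0 adjusted over the list alone) and no camera call. With the block members were called at 1000 IU/ml IFN epsilon in stress and immediate early response (5 higher and 1 lower of 33), cell cycle and proliferation (1 higher and 2 lower of 41) and ovarian epithelial and mesenchymal markers (1 higher of 30). At 1000 IU/ml IFN beta 1 ovarian epithelial or mesenchymal marker and 1 endothelial, fibroblast or adipocyte marker were higher with the block. Endothelial, fibroblast and adipocyte markers had medians of 0.06 and 0.05, with Fap (2.37 ± 0.56, adjusted p = 0.0391), a protease of activated fibroblasts, as the 1 member of 16 higher with IFN epsilon (1 adjusted over the list alone). Fap was well above background on 4 of 6 untreated arrays and differed by 2.22, 1.72 and 3.16 within dates. Interferon genes, with 5 members measured, had medians of 0.11 and 0.43 and 0 members called (0 adjusted over the list alone), and the IFN beta value had a camera adjusted p = 0.263 with an estimated correlation. Ifnb1, chosen after its values were seen, differed by 2.90 with 1000 IU/ml IFN epsilon (adjusted p = 0.453) and by 0.55 with IFN beta. NF-kB targets had 0 of 25 higher with 1000 IU/ml IFN beta (1 adjusted over the list alone) and MHC class II antigen presentation 0 of 10 (0 adjusted over the list alone).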

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

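The tests of a swap, of array quality, of leaving out arrays and of slides were chosen only after the results they measure were seen, as was a robust form of the pair comparison below.

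The 2 IFN beta arrays that the submitters left out had antiviral scores of 3.78 (labelled 10 IU/ml) and 4.16 (labelled 100 IU/ml), above the untreated samples (highest 0.23) and beside 4.21 on the 1000 IU/ml array of the same date. A swap with another sample of the series had against it that the lowest of the 9 strongly responding samples scored 2.67, above the 1.55 that was the highest of the remaining low-dose IFN beta samples, while a wrong dose or a swap from outside could not be tested. Brightness or quality had against it, for the array labelled 100 IU/ml, that 0 of 3 values lay outside the range of the date's other arrays, and stayed open for that labelled 10 IU/ml, with 1 of 3 outside (47.5% of probes above background, against 47.9% as their lowest). RNA of 1 culture on all 3 IFN beta arrays of that date may account for the likeness: over 11443 genes that passed no test, the SD of pair differences was at most 0.245 among these arrays and at least 0.251 among 24 other pairs. The 2 arrays of that date's untreated sample differed by 0.296 (robust SD 0.186), above all 3 IFN beta pairs. They lay on slides 1 and 2, while the IFN beta arrays labelled 100 and 1000 IU/ml shared slide 3. In a separate comparison, the untreated pair of date 2, on 1 slide, had a robust SD of 0.109. Those of dates 1 and 3, across slides, had 0.182 and 0.187. Slide was not accounted for in these SDs, so they do not mark shared RNA. The explanation by RNA of 1 culture stayed open too. A robust SD put only 2 of the 3 pairs below all others (highest 0.176, lowest other 0.140, the latter a pair on slide 2). A dosing error predicts the same, and no biological explanation was tested.

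The interaction of interferon and dose had a median of -1.13 over antiviral effectors. The camera adjusted p was 0.0362 with an estimated correlation, but 0.179 with the replicate block. The fry adjusted p was 0.382 without the block. The score interaction was -1.10 (95% confidence interval -2.08 to -0.12), or 0.05 with all 24 arrays and -0.56 on dates 1 and 2 only. In the fit without a block, date 3 was missing from IFN beta at 10 IU/ml but present at 1000 IU/ml. The 1000 IU/ml sample of date 3 scored 4.21, against 2.91 and 3.33 on dates 1 and 2. Whether the dose effect differs between the interferons therefore cannot be decided.

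Among the samples used, the antiviral score was higher with IFN epsilon than with IFN beta at 10 and 100 IU/ml. Within dates 1 and 2 the difference was 0.95 and 1.54 at 10 IU/ml and 1.36 and 1.82 at 100 IU/ml. No array of these dates was left out, so leaving out arrays cannot have made it there. On date 3 the left-out IFN beta arrays scored above IFN epsilon, 3.78 against 2.02 at 10 IU/ml and 4.16 against 3.37 at 100. With all 24 arrays the differences were 0.25 and 0.80, so their size depended on leaving out these arrays. Slide had against it the differences within the 2 slides that held both groups, 1.38 and 1.45 at 10 IU/ml and 1.36 and 1.82 at 100 IU/ml. Those at 100 IU/ml repeat the values within dates, because they rest on nearly the same samples. Those at 10 IU/ml compare samples of different dates. The calibration of the international units of each preparation and a difference in biology both stay possible, and neither was tested.

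Features without a gene name, 9737 of 24162 tested, responded as well. With IFN epsilon 11, 68 and 117 of them were higher than in untreated cells at 10, 100 and 1000 IU/ml, and with IFN beta 3 and 93 were higher at 100 and 1000 IU/ml. At 100 and 1000 IU/ml IFN epsilon 1 and 3 were lower.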

How the results depend on the processing

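The alternatives on dates 1 and 2 only, with unnamed features, and with all 24 arrays and the block were chosen only after the data were seen, and so was the use of the median signal in the normexp correction. Of 288 counts of genes under the alternatives 207 stayed within 1.5 times the reported count, and of 72 with a sample left out 49 did. Of 4883 calls on named genes 4111 were kept and 0 reversed, and of 1273 with a sample left out 950 were kept and 0 reversed. Most losses came with all 24 arrays (215 of 224), all 24 arrays and the block (148 of 224), only the groups compared (117 of 223) and median scaling (81 of 224). Of 3555 list values 3310 kept direction and side of the camera threshold at unadjusted p, 95 lost it, 134 gained it and 16 reversed, and of 900 with a sample left out 817, 40, 38 and 5 did. Directions of lists were first read from the median, which had 68 and 23 reversals, and then from the set test, which had 16 and 5. Where only 1 sample of a group was left, it was assumed to vary like the other groups. The filter then also kept probes that were well above background in that sample alone. With the strictest filter no interferon gene of that list was measured, so it has no value there. The number of arrays and the share of probes above background limit all of these values, and except where fewer samples or genes were used, the cause was not tested.

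After normexp together with quantile normalization, which changed background correction and scaling at once, the housekeeping median at 100 IU/ml IFN beta was 0.0334. There 38 genes differed between the interferons at 100 IU/ml. With the submitters' processed values these were 0.0351 and 35. Median scaling put the median gene at -0.435 at 1000 IU/ml IFN epsilon and at -0.19 at 1000 IU/ml IFN beta. With the reported scaling it lay at -0.052 and -0.042. Median scaling gave 173 genes at 1000 IU/ml IFN epsilon and 0 and 145 at 100 and 1000 IU/ml IFN beta. It gave 0 between the interferons at 10 and at 100 IU/ml, and 69 and 105 for the dose steps of IFN epsilon and IFN beta. Without a filter 6 genes differed between the interferons at 10 IU/ml. Testing every probe gave 21 between them at 100 IU/ml, and adding unnamed features 24 at 100 and 1 at 1000 IU/ml.

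With all 24 arrays limma called 0 genes at 10 and 100 IU/ml IFN epsilon, 71 at 1000, 0 at 100 and 1000 IU/ml IFN beta, 0 between the interferons at 10 and 100 IU/ml and 0 for both dose steps. The IFN beta chemokine median at 10 IU/ml was 0.14, and MHC class I antigen presentation between the interferons at 10 IU/ml turned to -0.19. The antiviral score was 1.478 and 2.34 with 10 and 100 IU/ml IFN beta, and the interferons differed by 0.25 and 0.80 at these doses. With all 24 arrays and the block the counts were 0, 41 and 904 (373 lower) for IFN epsilon at 10, 100 and 1000 IU/ml, 0 and 126 for IFN beta at 100 and 1000, 0, 0 and 1 between the interferons at 10, 100 and 1000, and 13 and 0 for the dose steps of IFN epsilon and IFN beta. There cell cycle and proliferation at 10 IU/ml IFN beta was 0.0555 and MHC class I between the interferons at 10 IU/ml -0.19.

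The replicate block gave 72, 234 (21 lower) and 1170 (517 lower) genes for IFN epsilon at 10, 100 and 1000 IU/ml, 42 and 497 (94 lower) for IFN beta at 100 and 1000, 53 between the interferons at 100, and 657 (168 lower) and 253 (22 lower) for the dose steps. Cell cycle and proliferation was 0.0595 at 10 IU/ml IFN beta and -0.0608 between the interferons at 100 IU/ml, and with an estimated correlation the block gained calls on endothelial, fibroblast and adipocyte markers for the dose steps of IFN epsilon (adjusted p = 0.0497) and IFN beta (0.0250). The block changed no other list call beyond those printed in the report. Block and slide together on single arrays gave 78, 421 (125 lower) and 2319 (928 higher and 1391 lower) for IFN epsilon, 66 and 892 (334 lower) for IFN beta at 100 and 1000, 24 and 83 between the interferons at 10 and 100, and 860 (254 lower) and 304 (36 lower) for the dose steps, with cell cycle and proliferation at 0.0460 and -0.0551 in the same comparisons as before. Single arrays with the sample as a random block gave 46 at 10 IU/ml IFN epsilon and 22 and 42 between the interferons at 10 and 100 IU/ml. With the second untreated array only, the interferon gene median at 10 IU/ml IFN epsilon was 0.0520.

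Fitting only the groups compared, with fewer samples to estimate the spread, gave 1 gene at 10 IU/ml IFN epsilon, 0 and 58 at 100 and 1000 IU/ml IFN beta, 0 between the interferons at 10 and 100, and 19 for the dose step of IFN beta. Array weights gave 54 and 596 (113 lower) at 10 and 1000 IU/ml IFN epsilon, 30 at 100 IU/ml IFN beta, 29 and 5 (4 lower) between the interferons at 100 and 1000, and 395 (27 lower) for the dose step of IFN epsilon. At an adjusted p under 0.01 limma called 6 and 150 at 100 and 1000 IU/ml IFN beta, 0 and 7 between the interferons at 10 and 100, and 82 and 102 for the dose steps.

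Dates 1 and 2 only gave 32 genes at 100 IU/ml IFN beta, 75 and 14 between the interferons at 100 and 1000, and 1 for the interaction. Endothelial, fibroblast and adipocyte markers at 10 IU/ml IFN beta were at -0.0792, and the score difference at 1000 IU/ml was 0.69. With the block on these dates the counts were 55 and 693 (158 lower) at 10 and 1000 IU/ml IFN epsilon, 44 at 100 IU/ml IFN beta, 140 and 57 between the interferons at 100 and 1000, 506 (53 lower) for the dose step of IFN epsilon and 1 for the interaction. Cell cycle and proliferation was then 0.0715 and 0.0473 at 10 and 100 IU/ml IFN beta and -0.0646 between the interferons at 100, and the endothelial, fibroblast and adipocyte markers stayed at -0.0792.

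With each sample left out in turn, the counts ranged from 0 to 29 at 10 and from 7 to 88 at 100 IU/ml IFN beta. Between the interferons they ranged from 0 to 35, 0 to 95 and 0 to 10 at 10, 100 and 1000 IU/ml. The dose step of IFN epsilon ranged from 82 to 124 and the interaction from 0 to 18. For IFN beta at 10 and 100 IU/ml, and between the interferons at these doses, the highest count rests on a single IFN beta sample. That of the interaction rests on a single sample of 10 IU/ml IFN beta. These highest counts are therefore no measure of how many genes changed. The antiviral median between the interferons at 1000 IU/ml ranged from -0.0177 to 0.524. Cell cycle and proliferation ranged from -0.0763 to 0.213 at 10 IU/ml IFN epsilon, and between the interferons from -0.121 to 0.259 at 100 and from -0.220 to 0.0698 at 1000. Apoptosis and cell death at 100 IU/ml IFN beta ranged from 0.0263 to 0.147.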

Other observations

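The test of the smaller MHC class I share was planned before its result was seen, as were those of the falls and of the other splits, while the genes named below, and the shares and test over members measured on every array, were chosen after the data were seen.

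The lists differed in how much of their log2 response to 1000 IU/ml IFN epsilon was reached at lower doses. Only the difference between MHC class I genes and antiviral effectors was tested. Each share below is a gene's log2 fold change at the lower dose divided by its log2 fold change at 1000 IU/ml. It is not the share of the change in signal itself, on which the lists were not compared. Among genes higher at 1000 IU/ml, the median share of that response reached at 10 IU/ml was 46.2% for 40 antiviral effectors, 50.6% for 7 genes of JAK-STAT and IRF signalling and 36.4% for 11 of nucleic acid sensing. It was 30.8% for 17 interferon-inducible GTPases, 27.6% for 17 genes of MHC class I antigen presentation, 19.6% for 8 of apoptosis and cell death, 15.5% for 6 of immune checkpoint and cell surface ligands and 8.93% for 6 chemokines and cytokines. Some members, such as Cxcl9, were not well above background in untreated cells, so their shares are not exact. Over members well above background on every array the share at 10 IU/ml was 46.3% for 39 antiviral effectors, 32.8% for 15 interferon-inducible GTPases, 27.6% for 17 of MHC class I antigen presentation, 22.2% for 4 of immune checkpoint and cell surface ligands and 13.5% for 3 chemokines and cytokines. At 100 IU/ml the shares were 85.5% for antiviral effectors, 72.3% for MHC class I antigen presentation and 58.8% for chemokines and cytokines. Over the same genes, chosen by their rise with IFN epsilon, IFN beta at 100 IU/ml reached 41.1% of its own 1000 IU/ml response in antiviral effectors. This share was 25.5% in MHC class I antigen presentation and 7.42% in immune checkpoint and cell surface ligands. The IFN beta shares set samples of dates 1 and 2 at 100 IU/ml against samples of all dates at 1000 IU/ml. The antiviral score at 1000 IU/ml IFN beta was 4.21 on date 3, against 2.91 and 3.33 on dates 1 and 2. The hypothesis that MHC class I genes reach a smaller share at 10 IU/ml IFN epsilon than antiviral effectors gave a difference of -18.6 percentage points and a permutation p over genes of 0.0011 (100000 resamples), or -18.7 points and 0.00133 over members measured on every array, although genes of the same samples are not independent replicates.

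Read from the line of IFN beta scores by dose, the antiviral score of 10 IU/ml IFN epsilon matched 139 IU/ml IFN beta, or 107 and 135 on the first and second date, 121 for the mean of these dates and 19.2 with all 24 arrays. That of 100 IU/ml matched 679 IU/ml, or 716 on the first date, 876 for the mean of the first and second and 499 with all 24 arrays, and on the second date it lay above the IFN beta range. The values of 139 and 679 IU/ml rest on 2 dates at 10 and 100 IU/ml IFN beta and on 3 at 1000 IU/ml.

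With the replicate number as a block, 517 genes were lower at 1000 IU/ml IFN epsilon, with a median of -0.36, 2 of them at least 2-fold lower and the largest at -1.28. In the fixed lists these were the death receptor Tnfrsf10b and the apoptosis regulators Bcl2 and Pmaip1 (3 of 36 lower and 13 higher in apoptosis and cell death), the mitotic genes Cdc20 and Birc5 (2 of 41 lower, 1 higher), the ligand Pvr (1 of 20 lower, 8 higher) and the immediate early gene Egr1 (1 of 33 lower, 5 higher). Of the 517, 62 were also among the 94 lower at 1000 IU/ml IFN beta, against 3.37 for independent lists, part of which may come from the shared untreated samples. A high background on the IFN epsilon array of the third date could have made such falls, but 327 genes were lower without it, 265 of them among the 517, and for the other falls, which lost their call with fewer samples, it stays open. Scaling could have made them as well. After quantile normalization 591 were lower, 453 of them among the 517. Without the block, the median gene at this dose was at -0.088 after quantile normalization and at -0.052 with the 75th percentile. Quantile normalization thus put the median gene lower still, so this test cannot decide whether scaling made the falls.

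All other splits of the same 6 samples gave fewer calls than the real groups for IFN epsilon at 10, 100 and 1000 IU/ml, IFN beta at 1000 IU/ml and the dose step of IFN epsilon. There the highest count in any other split was 0, against 29, 152, 333, 230 and 203, so 1 of the 10 splits reached the real count. For IFN epsilon against IFN beta at 1000 IU/ml all 10 splits reached the real count of 0, and the highest was 6. With 10 splits no share under 0.05 can arise, so chance can neither be excluded nor supported this way.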
